A study of Mus musculus with 6 samples.

How the data were processed

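Total RNA from mouse E14 embryonic stem cells was measured on 6 Illumina bead arrays. Per the labels, 3 samples carried the empty pSuper vector and 3 carried an shRNA against REST, both for 72 h. The labels state that RNA was purified with a DNase step and its quality checked, and that biotin-labelled cRNA was hybridized. The group and replicate number of each sample came from its title.

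The deposited table of raw values holds a linear intensity per probe and array, not normalized between arrays. From the values, each array was centred on its own negative-control background, since between 25.3% and 26.3% of its intensities lay below 0. The same deposited table holds a detection score per probe and array. Its header calls the score a p-value, but it rose with the intensity and reached 1 for the brightest probes, so 1 minus the score was used as the detection p. A further table, processed by the authors, holds a linear ratio per probe and array. Set against the intensities, each ratio followed from the intensity minus the array's lowest intensity, plus 0.1, times a factor per array, over a reference per probe. This held within 0.001 on the log2 scale for 100% of the values. The reference and the software behind both tables are not given in the sources used here.

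Background was corrected from the intensities and detection p with the normal-exponential model of limma 3.58.1 in R 4.3.3, as in its neqc function, with an offset of 16. Arrays were then quantile normalized and values put on the log2 scale. Of 25697 probes, the 12406 with a detection p under 0.05 on at least 3 of the 6 arrays were tested. The probe table used here gave a gene symbol to 23978 probes, and the other 1719, of which 737 were tested, stayed without a name. The tested probes with a symbol covered 8740 genes. A gene was represented by its tested probe with the highest mean over all arrays, whatever its change. Because the array probes carry no build in the sources used here, no genome positions are printed.

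Knockdown was compared with control by limma's linear model with moderated variance and group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all tested probes, and an adjusted p under 0.05 is called a change. Changes on the log2 scale are knockdown minus control, with the standard error (SE) of the model. Levels are means ± SD of 3 arrays. A gene below background on every array of a group has its fold given as a lower bound, set against the mean over those arrays of the lowest level that counted as above background. The number of arrays limits the precision.

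Before the data were examined, 17 gene lists were fixed: REST-repressed neuronal genes, REST corepressors, pluripotency, neural progenitors, broad neuronal genes, mesoderm, endoderm, trophoblast, fibroblast markers, interferon response, p53 targets, integrated stress and unfolded protein response, cell cycle, 2-cell-like and germline genes, glycolysis and hypoxia, imprinted genes, and housekeeping. The lists came from general knowledge, not from these samples. Each was tested against all other genes with camera at a preset correlation of 0.01 and adjusted over the 17 lists. Camera with an estimated correlation was run beside it, as was fry, which tests whether the genes of a list move on balance in 1 direction. The rule for named genes was fixed at the same time. It takes Rest, the 12 genes with the largest rise and the 12 with the largest fall among called probes whose groups did not overlap, the 8 members of the REST-repressed list with the smallest p, and the 4 such members of each other list. Genes named outside this rule were chosen after their values were seen. Further lists described in the closing section were written after the named genes had been seen.

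The other settings tried, all chosen at that time too, were no background correction, median scaling, the authors' ratios on the log2 scale, no filter, a filter at a detection p under 0.01 on all 6 arrays, an offset of 50, a trended and robust variance model, array weights, the replicate number as a block, a minimum fold of 1.5, the mean of a gene's probes, camera with an estimated correlation, and each array left out in turn. The fit was also tested on simulated data with 200 changed probes among 12406. It recovered 83% of changes of 1 on the log2 scale and 14% of changes of 0.5, and 3.96% of its calls were wrong. The simulated noise was independent between probes, and far more probes were called in the data (25.9% of those tested). These shares need not hold for the data.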

Results

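E14 is a mouse embryonic stem cell line, and REST is a transcriptional repressor that binds and silences many neuronal genes outside neurons. An shRNA is a hairpin RNA that lowers the level of the transcript it targets. Expression was measured in 3 samples with the empty vector and 3 with the REST shRNA, 72 h after treatment. The mean intensity per array ranged from 442 to 473, and between 46.4% and 49.0% of probes were above background. Over all tested probes, arrays of the same group correlated at 0.992 to 0.994 and arrays of different groups at 0.970 to 0.983. These correlations are across probes, which are not independent replicates. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. With 3 samples against 3, an exact permutation test of a single gene cannot give a p below 0.10.

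Rest itself could not be used to check the labels. Its only probe was not above background on any of the 6 arrays. The mean intensity was -0.03 ± 0.60 (SD, n = 3) in control and 0.63 ± 2.52 (SD, n = 3) in knockdown cells, where 0 is the background. A fold is not given, and the size of the knockdown is not known from these arrays.

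Members of the neuronal gene lists made up 7 of the 12 largest rises in REST shRNA cells. Gprin1, a neuronal growth-cone protein, rose 16.4-fold, from 5.36 ± 0.19 to 9.39 ± 0.09 on the log2 scale (SD, n = 3; limma adjusted p = 1.23e-06). The synaptic vesicle protein Syp rose 9.57-fold, from 7.22 ± 0.09 to 10.47 ± 0.16 (SD, n = 3; adjusted p = 1.79e-06). The secreted neuropeptide precursor Vgf rose 9.16-fold (log2 change 3.20 ± 0.14, SE, n = 3; adjusted p = 3.07e-06). Among the falls, the stress-inducible gene Gadd45g had the largest log2 change, -2.41 ± 0.18 (SE, n = 3; adjusted p = 0.000107), and its other tested probe gave -2.31.

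Further large rises included Scg5, a chaperone of neuroendocrine secretory granules (7.02-fold), Chrnb2, a nicotinic acetylcholine receptor subunit (6.65-fold), and Diras1, a small GTPase (6.50-fold). Cplx1, which acts in vesicle fusion, rose 5.85-fold, the cadherin Celsr3 5.42-fold and the necroptosis effector Mlkl 5.23-fold. Chrnb2 was above background on 1 control array, and Scg5 and Mlkl on 2, so these 3 folds are in part over background. With control arrays held at no less than their background level they were 5.52-fold, 6.38-fold and 4.90-fold. The glycosyltransferase Galnt9, the vesicle protein Syt4 and the G-protein regulator Rgs7 were below background on all 3 control arrays. Their folds are therefore lower bounds, at least 6.66-fold for Galnt9, at least 6.25-fold for Syt4 and at least 4.90-fold for Rgs7. The largest adjusted p among these 9 genes was 7.95e-05 (limma, n = 3 per group), for Chrnb2.

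Genes with the largest falls were of mixed function. Rgcc, a cell cycle regulator, had a log2 change of -2.04 ± 0.18 (SE, n = 3), and the transglutaminase Tgm2 one of -1.70 ± 0.12 (SE, n = 3). Gadd45b, a relative of Gadd45g, fell by 1.56 on the log2 scale, the lysosomal thiol reductase Ifi30 by 1.58, the neuropeptide Cort by 1.57, and Camk2n1, an inhibitor of CaM kinase II, and the ubiquitin ligase Mid1 by 1.55 each. Nxph4 and Islr2 were below background on all knockdown arrays and fell at least 2.37-fold and at least 2.09-fold. The largest adjusted p among these 9 genes was 0.00186, for Ifi30. Probes disagreed for a pair of genes: Hdlbp had a log2 change of -2.29 ± 0.10 (SE, n = 3) at its brightest probe and -0.14 ± 0.14 (adjusted p = 0.490) at another, and Cenpx had -1.52, -0.33 and -0.24 at its 3 probes, of which only the first passed the test.

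In all, 1590 probes rose and 1619 fell, together 25.9% of those tested, and they represented 1212 genes that rose and 1146 that fell. At least a 2-fold change was reached by 206 of the higher and 132 of the lower probes, and a 4-fold change by 20 and 4. The groups did not overlap for 43.3% of tested probes, against 10% by chance. In the authors' ratios, 2118 probes were higher and 907 lower, so that 70.0% of calls were higher against 49.5% here, with a median log2 change of 0.09 over all tested probes. Quantile normalization gave all arrays the same distribution of values, which holds the median change near 0 (-0.006 here). The even balance of calls here is therefore largely set by the scaling and cannot show a net rise or fall. Without control replicate 2 the counts were 1027 higher and 991 lower, and without knockdown replicate 3 they were 1029 and 1004.

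**Figure D1:**
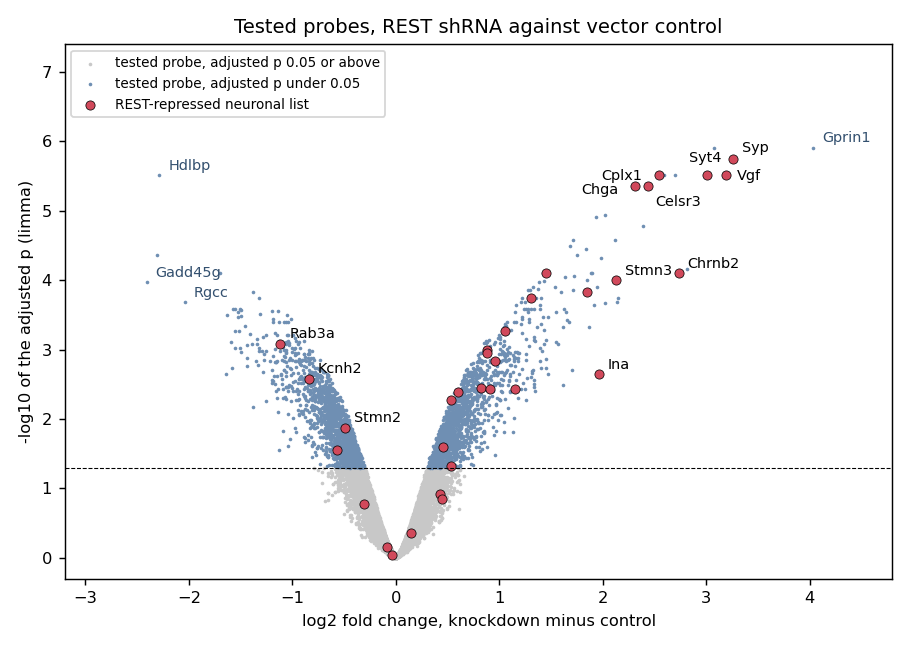
Log2 fold change (knockdown minus control, x axis) against -log10 of the limma adjusted p (y axis) for the 12406 tested probes, 3 arrays per group. Red points are the 33 tested REST-repressed neuronal genes, of which 23 rose and 4 fell, and the dashed line is an adjusted p of 0.05. Fitted changes are drawn for genes below background in a group, such as Syt4.

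REST-repressed neuronal genes rose as a group. Of 33 tested members, 23 rose, 4 fell and 6 were not called, with the same counts when adjusted over the list alone. The median log2 change was 0.88, and it stayed 0.88 with the 3 members that were below background in control cells at their bound (camera adjusted p = 2.30e-10). With an estimated correlation the adjusted p = 0.163, and fry gave an adjusted p of 0.000138. Besides Syp, Cplx1, Vgf, Syt4, Celsr3 and Chrnb2, the granule protein Chga rose 4.97-fold (log2 change 2.31 ± 0.11, SE, n = 3; limma adjusted p = 4.47e-06), with its 2 other probes also higher, and Rundc3a rose 2.73-fold. The 4 members that fell, named after their values were seen, were the vesicle GTPase Rab3a (-1.12), the potassium channel Kcnh2 (-0.84), the calcium channel Cacna1h (-0.57) and the microtubule regulator Stmn2 (-0.49). The last 2 were not called in the authors' ratios (adjusted p = 0.0602 and 0.0879), nor was Cacna1h without background correction (0.0688) or without any of the control replicates or knockdown replicate 3 (lowest 0.0574). A further 27 members with a probe were too dim to be tested, and over all 60 the median was 0.11 (camera adjusted p = 5.20e-09).

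**Figure D2:**
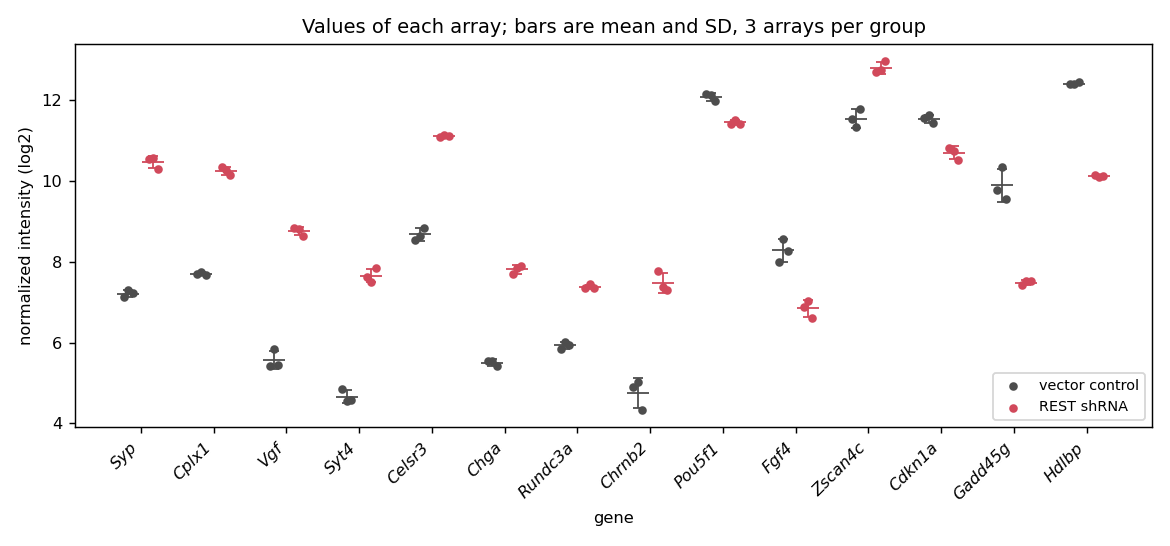
Normalized log2 intensity (y axis) on each array for 14 named genes (x axis), with 3 control arrays in grey and 3 knockdown arrays in red. Bars are the mean and SD of each group, and no control value overlaps a knockdown value of the same gene. The genes were picked by their change or p on these same arrays, so this lack of overlap was likely from the start.

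Neuronal genes beyond that list moved in both directions. Of 24 tested broad neuronal genes, 6 rose and 4 fell (6 and 6 adjusted over the list alone; camera adjusted p = 0.714), while 3 rose and 4 fell without knockdown replicate 2, and 8 fell with a trended robust fit. In fry, which compares the list with no other genes, they were higher on balance (adjusted p = 0.00625), but this rests on Gprin1, without which the mean log2 change was -0.03 in place of 0.14. Gprin1, the dendritic protein Map2 (1.84-fold) and Bex2 (1.72-fold) rose, and the vesicular glutamate transporter Slc17a7 had a log2 change of -1.06 ± 0.15 (SE, n = 3). Only 4 of 25 neural progenitor and neurogenic genes with a probe were bright enough to test. Otx2, a homeobox gene of the epiblast and forebrain, rose 3.12-fold, the intermediate filament gene Nes fell by 0.97 and Neurog3 by 0.66 on the log2 scale, and Neurog1 was not called (adjusted p = 0.549). The counts over that list alone were also 1 higher and 2 lower (camera adjusted p = 0.493).

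Among 21 tested REST corepressors and interacting chromatin proteins, 2 rose, 2 fell and 17 were not called, also when adjusted over the list alone (camera adjusted p = 0.903). The deacetylase Hdac1 had a log2 change of 0.63 ± 0.13 and the scaffold Sin3b one of 0.68 ± 0.16, whereas the methyltransferase Ehmt2 had -0.61 ± 0.10 and the remodeller Smarca4 -0.46 ± 0.10 (SE, n = 3). Sin3b was above background on only 1 control array, had 2.36 without background correction, where its call was lost (adjusted p = 0.161), as it was without knockdown replicate 2 (0.61, adjusted p = 0.0558), and Smarca4 was not called in the authors' ratios (adjusted p = 0.0854). The counts were 1 higher and 2 lower without background correction and without knockdown replicate 2, 2 and 1 in the authors' ratios, and 2 and 3 without control replicate 2.

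Pluripotency genes moved in both directions. Of 27 tested, 7 rose, 2 fell and 18 were not called, with the same counts adjusted over the list alone (median log2 change 0.00; camera adjusted p = 0.385). In fry the list was higher on balance (adjusted p = 0.0305). The growth factor Fgf4 fell by 1.44 ± 0.17 on the log2 scale and the core factor Pou5f1 by 0.63 ± 0.10 (SE, n = 3; limma adjusted p = 0.000873 and 0.00362). The LIF receptor Lifr rose 2.26-fold and Fbxo15 1.83-fold. Lifr was above background on 1 control array, and its fold was 2.11 with control arrays held at no less than their background level, while its log2 change was 1.17, or 2.03 without background correction. Sox2 (-0.19) and Nanog (-0.10), named after their values were seen, did not pass the test.

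Genes of the 2-cell-like state and the germline rose, with 6 of 11 tested members higher, none lower and 5 not called (camera adjusted p = 0.0155). With an estimated correlation the adjusted p = 0.295. Adjusted over the list alone, 6 were higher and 1 lower. Tex19.1, which acts in transposon control, rose 2.58-fold, the 2-cell-stage gene Zscan4c 2.39-fold, Tcstv1 1.92-fold and the germ cell factor Taf7l 1.77-fold. Over all 20 members with a probe, tested without the filter on dim probes, the camera call was lost (median 0.09, adjusted p = 0.0512).

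Targets of p53 fell, with 8 of 20 tested members lower, none higher and 12 not called, also adjusted over the list alone. The median log2 change was -0.27 (camera adjusted p = 0.000716). With an estimated correlation the adjusted p = 0.376. In the authors' ratios the median was -0.14, with 6 lower (camera adjusted p = 0.000923 at the preset correlation). The death receptor Fas fell by 0.94 ± 0.11, the cell cycle inhibitor Cdkn1a by 0.84 ± 0.12, the polymerase Polk by 0.71 ± 0.11 and the apoptosis gene Bbc3 by 0.62 ± 0.11 on the log2 scale (SE, n = 3).

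The other stress and metabolic lists missed the camera threshold. In the integrated stress and unfolded protein response, 8 of 19 fell and 2 rose (8 and 3 over the list alone; camera adjusted p = 0.201), against 6 and 5 in the authors' ratios and 4 that rose with an offset of 50 or a trended robust fit, with Ddit3 at -1.14 ± 0.19 and Nupr1 at -1.08 ± 0.14 (SE, n = 3). In glycolysis and hypoxia, 7 of 19 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.0794, but 0.0212 with median scaling and 0.0213 in the authors' ratios). The number lower was 9 with median scaling, 4 in the authors' ratios, 3 without background correction and 3 or 4 with any 1 array left out. The hypoxia-inducible genes Ndrg1 (-1.44 ± 0.20) and Vegfa (-1.11 ± 0.16) were lower, and the kinase Pdk1 (0.71 ± 0.15) was higher (SE, n = 3). Of 23 cell cycle genes, 5 fell, including Tk1 (-0.68), Ccnd1 (-0.62) and Cdk1 (-0.60), and 2 rose, including Ccne2 (0.65), with 6 and 2 adjusted over the list alone (adjusted p = 0.207). In the authors' ratios 3 fell and 3 rose, with median scaling 7 fell and 2 rose, with an offset of 50 and a trended robust fit 8 and 9 fell, and 3 fell and 1 rose without background correction and without control replicate 2, control replicate 3, knockdown replicate 2 or knockdown replicate 3, as against 4 and 1 without knockdown replicate 1. Of 9 interferon response genes 1 rose, the RNA-activated kinase Eif2ak2 (1.71-fold), 1 fell and 7 were not called, with the same counts over the list alone (adjusted p = 0.623). The gene that fell, Gbp2, was not called with median scaling, an offset of 50, a trended robust fit, the replicate block, in the authors' ratios or without any 1 array other than control replicate 1.

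Markers of other cell types missed the camera threshold, while in fry fibroblast, mesoderm and endoderm genes were lower on balance (adjusted p = 0.000707, 0.00723 and 0.0342) and trophoblast genes higher (0.00870). Of 11 fibroblast markers, 5 fell, among them Timp1 (-0.80 ± 0.10), Twist1 (-0.99 ± 0.17) and Mmp2 (-0.62 ± 0.13), while the collagen gene Col6a1 rose 3.28-fold (SE, n = 3; 6 lower and 1 higher over the list alone; camera adjusted p = 0.0794). Col6a1 was above background on 2 control arrays, and its fold was 3.19 with control arrays held at no less than their background level. Without control replicate 2, 3 fibroblast markers fell. Of 13 mesoderm genes, 4 fell, including Fgf8 (-1.08, but -1.91 without background correction) and Gata2 (-1.04), and 2 rose, including Isl1 (0.68), with 4 and 2 over the list alone (adjusted p = 0.207), but only 1 rose without background correction, with the replicate block or without any 1 array other than control replicate 1. Of 13 endoderm genes, 4 fell, including the keratin Krt8 (-0.84) and Sparc (-0.73), and 1 rose, Dab2 (0.48), with 5 and 1 over the list alone (adjusted p = 0.231), but only 2 fell without control replicate 2 or knockdown replicate 3. Trophoblast genes had 5 higher, including Tfap2c (1.78-fold), and 1 lower of 8, also over the list alone (adjusted p = 0.138), but 3 higher without control replicate 2, control replicate 3 or knockdown replicate 3.

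Imprinted genes had 4 lower and 2 higher of 15 (5 and 3 over the list alone; camera adjusted p = 0.201). None was higher without control replicate 1, control replicate 2 or knockdown replicate 3, and 1 was without knockdown replicate 2. The growth inhibitor Cdkn1c fell by 1.29 ± 0.16 and the transporter Slc22a18 by 0.92 ± 0.11 on the log2 scale (SE, n = 3). The housekeeping gene Pgk1, which is also counted in the glycolysis and hypoxia list, had a log2 change of -0.72 ± 0.11 (SE, n = 3). Of 11 housekeeping genes, 3 fell and 2 rose, also over the list alone (adjusted p = 0.581). None rose and 1 fell without control replicate 1, control replicate 2 or knockdown replicate 3, none rose and 2 fell without knockdown replicate 1, 1 rose and 2 fell without knockdown replicate 2 or without background correction, 1 rose and 3 fell without control replicate 3, with median scaling or with the replicate block, and 2 rose and 1 fell in the authors' ratios. Of the 17 lists, the REST-repressed, p53 and 2-cell-like lists passed camera at the preset correlation. None passed with an estimated correlation (lowest adjusted p = 0.163). The estimates were 0.056, 0.175 and -0.056 for these lists. For the 2-cell-like list the estimate lay below the preset of 0.01, yet its unadjusted camera p rose from 0.00274 to 0.0348. A higher correlation among its members is therefore not why that call was lost. In fry, 12 of the 17 lists moved on balance in 1 direction.

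**Figure D3:**
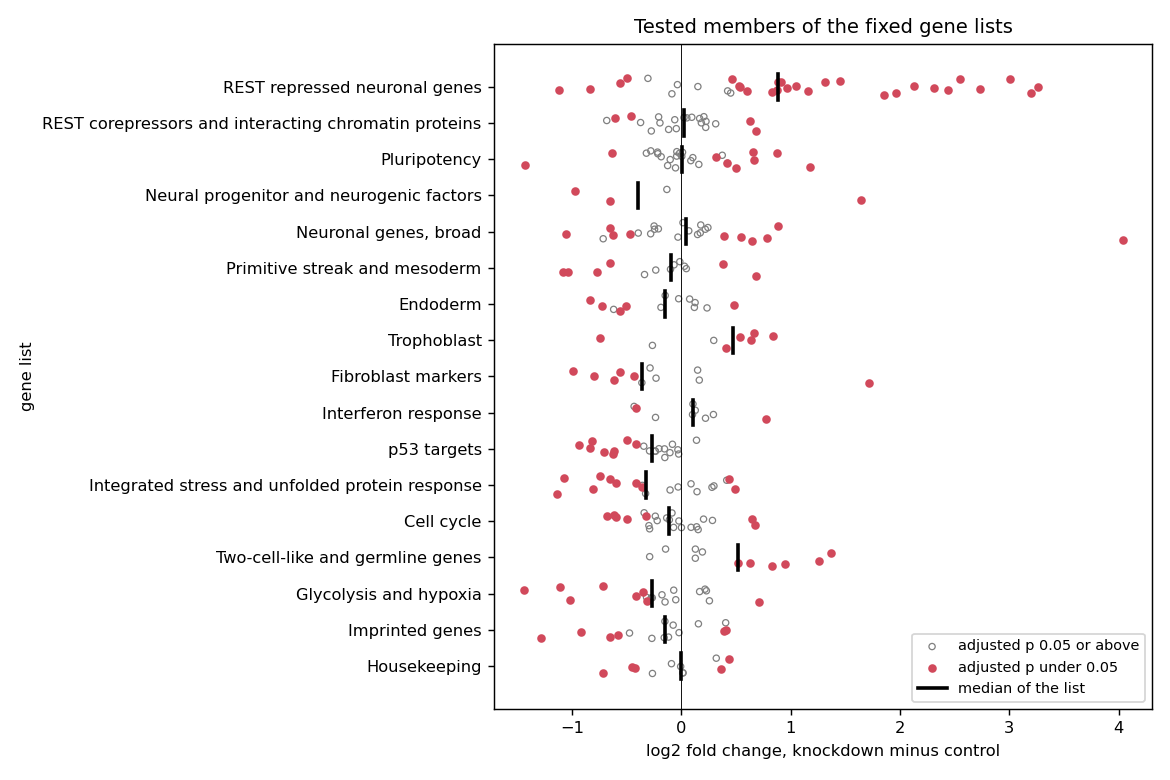
Log2 fold change (knockdown minus control, x axis) of each tested member of the 17 gene lists (y axis). Filled points have a limma adjusted p under 0.05, open points do not, and black bars are list medians, from -0.39 for neural progenitor genes to 0.88 for REST-repressed neuronal genes.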

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

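The REST-repressed list stayed higher past the camera threshold under each alternative except an estimated correlation (same median 0.88, adjusted p = 0.163). Its adjusted p ranged otherwise from 2.38e-12 to 3.12e-05, and its median from 0.11, without the filter and with 60 genes, to 1.00 in the authors' ratios. Leaving out each array in turn gave 0.86 to 0.91 for the list, 1027 to 1355 probes higher and 991 to 1370 lower. The lowest counts came without control replicate 2 and without knockdown replicate 3. These arrays correlated least of all pairs across groups (0.970), and the cause of the lower counts was not tested. The authors' ratios gave 907 lower probes (of these, 886 were among the 1619), and a minimum fold of 1.5 left 819 higher and 759 lower. With the replicate block, 1417 were higher and 1463 lower, with a list median of 0.88 (adjusted p = 1.17e-09). Deviations of arrays with the same number correlated at -0.06, 0.03 and 0.04, so the numbers were not taken as pairs. No gene named by rule reversed, though without background correction the log2 change of 13 of the 85 called was over 1.5 times larger. The rule picked genes by their change or p on these same arrays, so reversals were unlikely from the start. The minimum fold aside, 36 calls of named genes were lost, all of Gbp2, Tfrc, Tbp, Rpl4, Apoe, Sin3b or Smarca4. With the strict filter only 65 of the 88 named genes apart from Rest were tested. The others, among them Galnt9, Syt4 and Rgs7, gave no value there and are not counted as lost. Rest stayed below background under each filter, had an adjusted p of 0.950 when tested without a filter, and gave no value in other settings. Fibroblast and trophoblast lists passed camera only with the strict filter (adjusted p = 0.0104 and 0.0378). A chip block was not run, because the tables used here name no chip. Genes near background, such as 27 of 60 REST-repressed genes, were beyond what these signals can show.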

Other observations

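The gene groups in this part were written after the named genes had been seen, and the tests on collagens and on factors set anew were chosen only after the result was seen. Ion channels outside the REST-repressed list had 4 higher and 1 lower of 11 tested members (camera adjusted p = 0.611 over 9 such groups). The sodium channel subunit Scn3b had a log2 change of 2.02 ± 0.18, the potassium channel Kcnc1 one of 1.33 ± 0.21, the pacemaker channel Hcn3 1.08 ± 0.13 and the calcium channel Cacna1b 0.75 ± 0.15, while Kcnh3 had -1.09 ± 0.26 (SE, n = 3), and without background correction -2.65 ± 1.28, where the call was lost (adjusted p = 0.195), as it was without control replicate 3 (-0.92, adjusted p = 0.0532). Scn3b was above background on 1 control array, Kcnc1 and Cacna1b on 2, and Kcnh3 on 2 knockdown arrays, so these changes are in part over background. Without background correction Scn3b had 3.29 ± 0.56 and Cacna1b 1.19 ± 0.30. Among 17 other secretory granule and vesicle genes, 3 rose, Scg5, Rims2 (1.07) and Nsf (0.48), and 4 fell, including the vesicle proteins Syngr1 (-1.19) and Sv2a (-1.19), at a camera adjusted p of 0.611.

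Of 10 tested linker and core histone genes, 5 fell and none rose. The 5 not called ranged from a log2 change of -0.40 for H2ac4 to 0.27 for H3f3b. The median log2 change of the group was -0.49 (camera adjusted p = 0.0400). With an estimated correlation the adjusted p = 0.793, and at the preset correlation it was 0.0566 without background correction, 0.0712 without control replicate 2 and 0.0653 without knockdown replicate 2. H4c4 had -0.95 ± 0.19, H2ax -0.69 ± 0.14 and H1f2 -0.69 ± 0.14 (SE, n = 3), and H1f1, below background on all knockdown arrays, fell at least 1.98-fold. Cholesterol synthesis genes had 4 lower, including Msmo1 (-0.70), and none higher of 13 (camera adjusted p = 0.0409). With an estimated correlation the adjusted p = 0.645, and at the preset correlation it was 0.105 in the authors' ratios, with 1 lower, and 0.0566 without background correction, with 2 lower. Its camera call was also lost without control replicate 1, control replicate 2 or knockdown replicate 2 (adjusted p = 0.0922, 0.0712 and 0.0817), with 1 lower each, and 1 was lower without control replicate 3 and 2 without knockdown replicate 3. Of 5 BMP and Id genes, Id3 rose (0.78, and 1.27 without background correction), while Id2 (-0.49) and Smad6 (-0.39) fell (camera adjusted p = 0.776). Id3 was above background on 2 control arrays. Only 1 fell without background correction, in the authors' ratios or without any 1 array other than knockdown replicate 2.

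REST-repressed neuronal genes were higher by a median of 0.88. If neurons in the knockdown cultures were the source, their abundant transcripts would be above background there. Of 16 such transcripts, 6 (Gap43, Nefm, Stmn4, Syt1, Elavl4 and Ncam1) were below background on all 3 knockdown arrays. Weak probes would give the same, and 27 of 60 REST-repressed genes were also too dim to test, so these 6 decide nothing. Of 10 tested, 3 rose and 3 fell, which shows no shared rise, but neurons as a source stay open. Normalization is argued against, since the lowest median under the 3 other scalings was 0.91. Loss of pluripotency stays open, because the pluripotency genes moved both ways (median 0.0033), on balance higher in fry (adjusted p = 0.0305), and the mean of -0.31 over Pou5f1, Sox2 and Nanog rests on Pou5f1, the only one of these that passed the test. The arrays make 10 splits into 3 and 3, too few for a share under 0.05, and 1 of the 10 splits, the real one, gave values as large: 1590 higher and 1619 lower probes and a list median of 0.88, against 0, 0 and 0.39 at most in the others. Each of the other splits put arrays of both groups on each side, so the group difference itself added to the spread. Few calls were therefore likely there in advance, and the splits decide nothing.

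Most called probes were higher in the authors' ratios (70.0%). With a common shift in place of each array's lowest signal and the authors' factors kept, 77.8% were higher. Those factors match medians taken after that subtraction, as given below. Keeping them does not remove its effect, so this test leaves the subtraction undecided. Centring each array on its median over the tested probes gave 53.7% higher, but it fixes that balance and so leaves the authors' factor per array alone undecided. Each factor times the median of the shifted intensities of all probes was 38.8 on every array, so the authors' arrays already shared a median before the reference per probe was applied. With a common shift and factors set anew on the median of all probes, 49.7% were higher. The excess of higher probes may therefore come from factors set on a median that holds each array's lowest signal, and no biological explanation of it was tested.

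Of 11 fibroblast markers 5 fell in knockdown cells and 1, the collagen gene Col6a1, rose. The list missed the threshold (median log2 change -0.36, camera adjusted p = 0.0794). A first test of fewer fibroblasts in the knockdown cultures left this open, because 1 of 3 fibroblast collagens, Col1a2, was above background on 1 control array. A second test, with its bound set when the collagen values were already known, compared levels. The highest mean control intensity of the 3 collagens was 11.9, against 501 lost by Timp1, but intensities of different probes are not on the same scale, so this decides nothing either. Fewer fibroblasts therefore stay open.

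A hypothesis of lower FGF and ERK signalling, drawn from the fall of Fgf4, was tested on 14 ERK feedback genes. Their median log2 change was 0.074 (0.030 without control replicate 2 and 0.139 in the authors' ratios), with an SD over members of 0.65. Of these genes, 5 rose, including Spry4 (1.34 ± 0.22, SE, n = 3) and Dusp6 (1.04 ± 0.11). Another 3 fell, including Ier3 (-0.96), or 1 without any 1 control replicate and 2 without any 1 knockdown replicate. The median lay above the bound set before the test as going against lower signalling. Members went both ways with a wide spread, however, so the test does not decide. Their mean log2 change was 0.13, with a camera adjusted p of 0.611 and a fry adjusted p of 0.0358. Nfe2l2, the gene of the oxidative stress factor NRF2, had a log2 change of -1.49 ± 0.14 (SE, n = 3; limma adjusted p = 0.000273), and its other probe was below background. Lower NRF2 target expression was tested on 14 targets, whose median was -0.11. It was 0.03 in the authors' ratios, -0.06 without control replicate 1 and 0.006 without knockdown replicate 3. Of the targets, 1 was higher and 2 lower, against 1 and 0 in the authors' ratios. The counts were 0 and 2 without background correction, control replicate 1 or knockdown replicate 1, 0 and 1 without control replicate 3, and 1 and 1 without knockdown replicate 2. None was called without control replicate 2 or knockdown replicate 3, so lower target expression stays open.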
